A study of Homo sapiens with 6 samples.

How the data were processed

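RNA from SH-SY5Y cells, a human neuroblastoma line with neuronal features, was measured on 6 single-colour Cy3 arrays of 1 design, a custom Agilent array for coding and long non-coding transcripts. The labels give 2 groups of 3 biological replicates: cells kept for 24 h with 1 µM MI-773, and cells kept for 24 h with the vehicle, DMSO. MI-773 is a small-molecule inhibitor of MDM2. Per the labels' protocols, ribosomal RNA was removed before amplification and labelling. The labels do not say whether the biological replicates came from separate cultures or days, so p-values measure only the spread between these samples.

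The authors deposited 1 Agilent Feature Extraction table per array, made with Agilent Feature Extraction 11.0.1.1 per the submitters' processing notes. Per the file headers, these tables hold intensity values per spot: the median pixel brightness, the local background, a background-subtracted signal, and a processed signal. The processed signal was above 0 on dim spots too, while the background-subtracted signal fell below 0 on some, and its 75th percentile still differed between arrays. The authors also deposited a table of log2 values with 1 row per probe. Its method is not given in the sources used here. Its columns had a median of 4.47 on every array and differed by at most 0.00021 at the 75th percentile, and each correlated with log2 of the processed signal of its own array at 0.987 to 0.998. Its scale is therefore taken as log2, without centring per gene, with the arrays brought to nearly the same median and 75th percentile. Which method did so is not given, but its results below lay close to those of quantile normalization. In limma, 29113 probes passed with it and 28699 with quantile normalization, and PGK1 differed by -0.1542 and -0.1564. These 2 settings are therefore not separate checks.

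Each array held 62903 spots. The spots comprised 60904 probes with a manufacturer's number, spotted once each, 20 probes with a RefSeq accession, spotted 10 times each, and control spots. The 60 sequences named Negative were treated as controls. Neither the files nor the reference table used here pair the manufacturer's numbers with genes, with genome positions or with a coding or non-coding class. Only the 20 RefSeq accessions could be named, and all 20 matched a symbol in the NCBI table of assembly GRCh38.p14; the array grid refers to hg19, so no coordinates are given. The planned comparison of coding with non-coding probes was not made. The 25 gene lists fixed before the data were examined had at least 5 named members in 0 cases, so no set test was run; named members of 2 lists are reported.

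Spots that the scanner software marked as non-uniform or as population outliers were left out (7 to 25 spots per array), and no spot was saturated. Processed signals were put on the log2 scale, the 10 spots of a RefSeq probe were averaged, and the 75th percentile over the 60924 probes was subtracted on each array, so that levels are log2 signals relative to that percentile. Between 53.5% and 67.5% of probes were well above background on each array, which kept the percentile over all probes as the main setting. A probe was tested if it was well above background on at least 3 of the 6 arrays, whatever their group; this kept 40119 probes (65.9%). A probe spotted 10 times counted as well above background where most of its spots were.

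Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, treatment as the only term, all 6 arrays), with Benjamini-Hochberg adjustment over the tested probes and a threshold of 0.05. Single values per array were compared with exact two-sided permutation tests, which cannot go below 0.1 with 3 arrays against 3. The number of arrays limits the precision. Where a probe was not well above background on any array of a group, a bound on its fold change was computed apart from the fit. It sets the mean of the bright group against a mean for the dim group. Each array of the dim group enters with the higher of the probe's own signal and the lowest signal among probes well above background. Counts by fold size and medians by level use the fitted differences of all tested probes, such probes included.

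The rule for named genes was also fixed before the data were examined and took genes by symbol: a few fixed ones, members of the lists and those with the most marked changes. Of the 20 symbols at hand, 18 are reported and the others are not reported here, and the parts of the rule that need names for the manufacturer's probes were not applied. The 2 highest and the 2 lowest changes among probes well above background on all 6 arrays are given by number, a choice made after the absence of names was known.

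The test was checked on simulated arrays drawn from the means and spreads of the 40119 tested probes, with 200 of them changed. It recovered 81.8% of changes of 2 on the log2 scale, 56.7% of changes of 1 and 0% of changes of 0.5, with 6 false calls among 98. With so few probes changed, the adjustment is stricter than in the data, where 78.8% of tested probes passed. These shares therefore do not give the recovery in the data, where smaller changes could pass. Alternatives covered background correction, scaling, the filter on dim probes, outlier spots, the variance model, the replicate number as a block, the slide, the authors' log2 table and each array left out in turn. Normexp background correction (offset 50) used the median pixel signal, and the mean signal planned for it was not used here. The offset was added to every spot. Median processed signals were 20.4 to 33.9 per array, so the offset itself shrinks log2 fold changes of dim probes. Effects of the offset and of the background correction were not separated. All arrays carried 1 scan time, so a block for the scan could not be fitted. All 3 MI-773 arrays and DMSO replicate 1 lay on slide 1, and DMSO replicates 2 and 3 on slide 2. Per-array checks and figures used Python 3.11.15 with scipy 1.17.1.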

Results

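Expression was profiled in SH-SY5Y neuroblastoma cells after 24 h with 1 µM MI-773 or with DMSO, with 3 arrays per group. The design asks which coding and long non-coding transcripts differ after 24 h with an inhibitor of MDM2, a ubiquitin ligase. Of the 60924 probes on each array, 18 are reported by gene; the others are described as a set. The 75th percentile of the processed signal lay between 187 and 200.3 on the MI-773 arrays and between 182 and 192 on the DMSO arrays.

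Among these 18 genes, most of them genes that nearly all cells express, 1 rose after MI-773, 5 fell and 12 did not pass the threshold, by their RefSeq probes. PRMT1, a protein arginine methyltransferase, fell by 0.50 on the log2 scale (SE 0.09, limma adjusted p = 0.0018), from 8.74 ± 0.07 to 8.25 ± 0.06 (SD, n = 3) relative to the 75th percentile. PGK1, a glycolytic kinase, fell by 0.43 (SE 0.13, limma adjusted p = 0.016) and MTX1, a protein of the mitochondrial outer membrane, fell by 0.41 (SE 0.10, limma adjusted p = 0.0089). ARHGDIA, a GDP dissociation inhibitor, and the actin-binding protein PFN1 both fell by 0.35 (SE 0.09 each, limma adjusted p = 0.011 and 0.010). The gene that rose was GRM4, a metabotropic glutamate receptor, by 0.87 (SE 0.12, limma adjusted p = 0.00060). The groups did not overlap in these 6 genes, nor in 8 of the 12 that did not pass. The size of the GRM4 difference lay between 0.11 and 1.16 over its other settings (limma adjusted p between 3.3e-05 and 0.39). The lowest p came from a fit with weights per array, whose estimation did not converge. The difference was 0.23 under normexp, 0.23 under quantile normalization, 0.24 under median scaling, 0.30 in the authors' log2 table and 0.11 under cyclic loess. The GRM4 probe was dim, and the normexp offset shrinks changes of such probes. It was well above background on all 3 MI-773 arrays and on 2 of the 3 DMSO arrays. Tested probes as a set also moved with level. At mean levels from 1.383 to 10.134, where all 5 falls lay, the median log2 fold change was -0.40, with quartiles of -0.80 and 0. The 5 falls were thus typical of bright probes. At mean levels from -4.995 to -2.868, where GRM4 lay, the median was 1.24, above the GRM4 rise. Which probes are tested there depends on the filter.

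These calls depended on the scaling to different degrees. PRMT1 passed in 19 of 21 other settings, with log2 fold changes between -1.12 and -0.11 (limma adjusted p between 3.5e-05 and 0.25), and 0 of the 6 genes in limma passed in every setting run. Over the 6 other scalings, the call of PRMT1 held in 4, that of GRM4 in 3, that of MTX1 in 2, and those of PGK1, ARHGDIA and PFN1 in 1 each. The sign turned under cyclic loess for MTX1 (0.0003), ARHGDIA (0.0521) and PFN1 (0.0326), and for ARHGDIA in the authors' log2 table as well (0.0007). With the slide as a block, as with slide 1 alone, the differences rest on DMSO replicate 1, the only DMSO array on slide 1. They were then -0.32 for PGK1, -0.39 for ARHGDIA, -0.57 for PRMT1 and 0.82 for GRM4. PGK1 lost its call in 9 of its 21 other settings (limma adjusted p between 0.00034 and 0.47). One of these left out MI-773 replicate 2 (-0.43, limma adjusted p = 0.051).

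**Figure D1:**
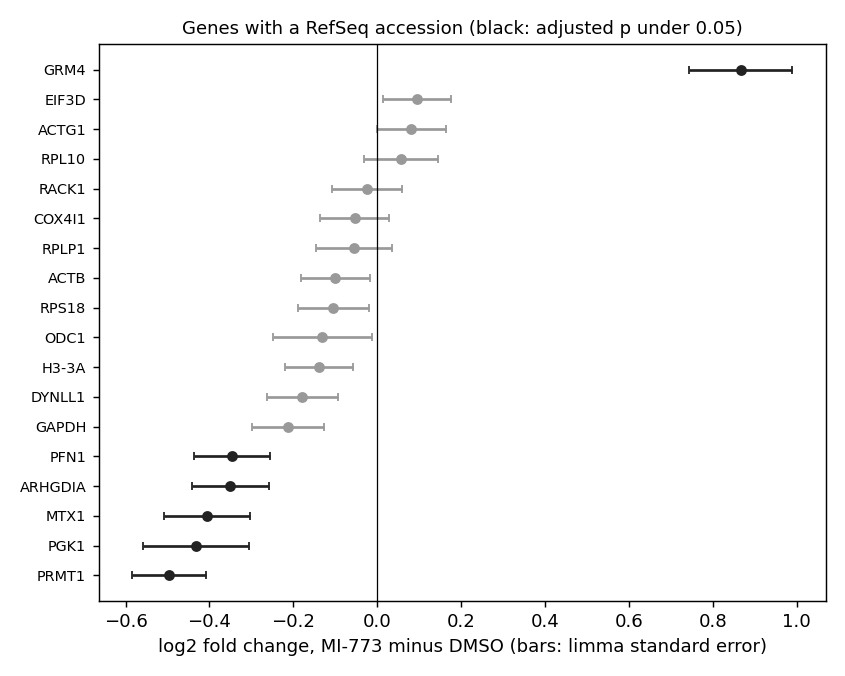
Log2 fold change (MI-773 minus DMSO) of the 18 reported genes with a RefSeq accession, with limma standard errors as bars; black points passed an adjusted p of 0.05 and grey points did not. At this scaling GRM4 is highest at 0.87, PRMT1 is lowest at -0.50, and 12 genes lie between -0.21 and 0.09, where signs turn with the scaling; EIF3D exceeds GRM4 under quantile normalization, cyclic loess and in the authors' log2 table.

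The 12 genes that did not pass had log2 fold changes between -0.21 and 0.09 and limma adjusted p-values between 0.054 and 0.80, and the sign of each turned under at least 1 other scaling. Under median scaling all 12 passed the threshold in limma as falls; under cyclic loess 9 passed as rises, RPL10 passed as a fall, and GAPDH and DYNLL1 did not pass. ACTB and ACTG1, the cytoplasmic actins, stood at -0.10 (SE 0.08) and 0.08 (SE 0.08). COX4I1, a subunit of cytochrome c oxidase, stood at -0.05 (SE 0.08). The ribosome-associated scaffold RACK1 stood at -0.02 (SE 0.08) and the translation initiation factor EIF3D at 0.09 (SE 0.08), but EIF3D passed as a rise under 5 of the 6 other scalings (0.23 to 0.48) and as a fall under median scaling (-0.53). ODC1, the first enzyme of polyamine synthesis, stood at -0.13 (SE 0.12), the replacement histone gene H3-3A at -0.14 (SE 0.08) and the dynein light chain DYNLL1 at -0.18 (SE 0.08).

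Of the gene lists fixed before the data were examined, members of 2 are reported. Among ribosomal proteins, 0 of 3 named members passed the threshold in limma, over all probes or adjusted over these 3 alone. RPLP1 stood at -0.06 (SE 0.09), RPS18 at -0.10 (SE 0.09) and RPL10 at 0.06 (SE 0.09), with unadjusted p-values of 0.26 to 0.56 and signs that turned with the scaling. The RPL10 probe was dim, although well above background on all 6 arrays. Its mean level was -2.79, against 9.86 for RPLP1 and 9.90 for RPS18, so its changes are those of a dim probe. RPL10 passed as a fall under median scaling (-0.5704), quantile normalization (-0.5485), cyclic loess (-0.6371) and in the authors' log2 table (-0.5201), and as a rise of 0.35 under the percentile over probes well above background on all 6 arrays (limma adjusted p between 0.00078 and 0.99 over its other settings). RPLP1 and RPS18 passed as falls under median scaling (-0.68 and -0.73) and as rises under cyclic loess (0.29 and 0.24). Of 2 hypoxia-induced glycolytic genes, PGK1 passed over all probes by its RefSeq probe. GAPDH did not (-0.21, SE 0.09, limma adjusted p = 0.054). Adjusted over these 2 genes alone, not over the whole list, limma adjusted p was 0.023 for PGK1 and 0.043 for GAPDH. That value of GAPDH equals its unadjusted p. Both genes lay among the brightest probes, where the median log2 fold change was -0.40, so they give no result for the list. GAPDH passed over all probes as a fall in 5 of its 21 other settings. Its sign turned under cyclic loess (0.1445) and under the percentile over probes well above background on all 6 arrays (0.0813). The other lists, among them those of cell cycle and apoptosis genes, were not analysed here.

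Control spots hold further probes for the 3' and 5' parts of GAPDH and PGK1, and for PGK1 they disagreed with the RefSeq probe. After MI-773 the PGK1 3' probe was higher than after DMSO by 0.21 on the log2 scale, without overlap between groups (exact permutation p = 0.1). It stood at 8.40 ± 0.09 against 8.19 ± 0.08 (SD, n = 3). The PGK1 5' probe differed by 0.02 (exact permutation p = 0.9), at 2.24 ± 0.23 against 2.22 ± 0.15 (SD, n = 3). The RefSeq probe, at 1.92 ± 0.20 against 2.35 ± 0.10 (SD, n = 3), was far dimmer than the 3' probe. Whether PGK1 transcripts fell is therefore not settled. The GAPDH 3' probe differed by -0.25 (exact permutation p = 0.1) and its 5' probe by -0.01 (exact permutation p = 1.0). The log2 ratio of 3' to 5' signal, which rises as RNA degrades, was 1.79 ± 0.13 after MI-773 and 2.04 ± 0.09 after DMSO for GAPDH (SD, n = 3, exact permutation p = 0.1), and 6.16 ± 0.15 and 5.97 ± 0.07 for PGK1 (SD, n = 3, exact permutation p = 0.2). With 3 arrays against 3, 0.1 is the smallest p these two-sided tests can give.

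Over all probes, most transcripts measured differed between the groups. Of 40119 tested probes, 31594 (78.8%) passed an adjusted p of 0.05 in limma, 17263 of them higher and 14331 lower after MI-773. A fitted difference of at least 2-fold was reached by 11255 higher and 5734 lower probes, among them probes well above background in 1 group only. Testing only probes well above background on all 6 arrays turned this balance to 4815 higher and 5050 lower. Normexp background correction, whose offset shrinks changes of dim probes, gave 2628 higher and 2908 lower. Median scaling gave 6211 higher and 13608 lower. A fitted difference of at least 8-fold was reached by 1437 higher and 99 lower probes. Among probes well above background on all 6 arrays, these numbers were 163 and 43. The median absolute log2 fold change over the tested probes was 0.85, against a median standard error of 0.13. The groups did not overlap in 32861 probes (81.9%), where chance gives 10%. Arrays of the same group correlated across probes at 0.991 to 0.996, and arrays of different groups at 0.897 to 0.924. Slide 2 held DMSO arrays only. With the slide as a block, the difference is therefore that of the MI-773 arrays from DMSO replicate 1, as it is with slide 1 alone. These 2 settings are not separate checks, and neither has replicates in DMSO.

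The balance of higher and lower probes followed the scaling and the filter on dim probes. Higher probes made up 54.6% of the calls at the 75th percentile of all probes, 33.5% when each array was scaled to its median, and 66.8% when the percentile was taken over probes well above background on all 6 arrays. At the main scaling, testing only probes well above background on all 6 arrays gave 10084 higher and 13808 lower, or 42.2% higher. The median, over the tested probes, of the change in a probe's log2 fold change was -0.63 and 0.29 under these 2 scalings, -0.21 under quantile normalization, -0.10 under cyclic loess and 0.14 under scaling on the RefSeq probes. Directions of small changes are therefore relative to the chosen scale.

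Among probes well above background on all 6 arrays, the most marked rises belonged to 2 probes not paired with a gene here. ASHGV40054129 rose by 6.28 on the log2 scale (SE 0.15, limma adjusted p = 7.0e-07), 77.5-fold, from -2.85 ± 0.26 to 3.43 ± 0.14 (SD, n = 3) relative to the 75th percentile. ASHGV40037674 rose by 6.20 (SE 0.10, limma adjusted p = 5.9e-07), 73.5-fold. The most marked falls were smaller. ASHGV40040040 fell by 4.19 on the log2 scale (SE 0.13, limma adjusted p = 1.3e-06), 18.3-fold, and ASHGV40005655 fell by 4.18 (SE 0.23, limma adjusted p = 8.0e-06), 18.2-fold. All 4 kept their direction and passed the threshold in each of the 21 other settings, but under normexp the rises were 4.57 and 4.82 on the log2 scale and the falls -3.53 and -3.09, in the order named.

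The share of probes well above background was 67.3% ± 0.32 (SD, n = 3) on the MI-773 arrays and 54.8% ± 1.33 (SD, n = 3) on the DMSO arrays, a difference of 12.5 percentage points with no overlap between groups (exact permutation p = 0.1). On slide 1, where 1 DMSO array lay beside the MI-773 arrays, that array detected 56.2%. In all, 5371 probes were well above background on all 3 MI-773 arrays and on no DMSO array, and 381 showed the opposite. Among the 5371, 1907 passed the threshold with a bound of at least 2-fold, the highest being at least 57.7-fold; among the 381, 192 did so, the highest being at least 9.90-fold.

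**Figure D2:**
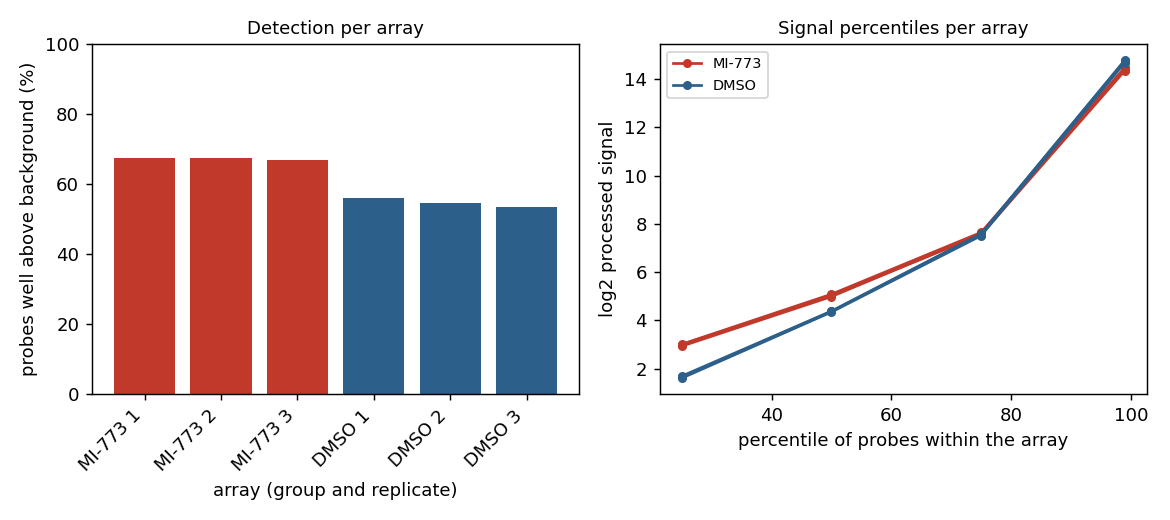
Left, percent of the 60924 probes well above background on each of the 6 arrays, by group and replicate. Right, log2 processed signal at the 25th, 50th, 75th and 99th percentile of the probes of each array, 1 line per array. The MI-773 arrays detected 66.9% to 67.5% of probes and the DMSO arrays 53.5% to 56.2%; the lines meet at the 75th percentile and cross above it.

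The differences varied with signal level. Of 4 bins of tested probes of equal size by mean signal, the dimmest held 6935 rises and 1123 falls, with a median log2 fold change of 1.24. The second held 5005 rises and 2859 falls, and the third 3655 rises and 4562 falls. In the brightest, 1668 rose and 5787 fell, with a median of -0.40. Which probes are in these bins depends on the filter, which 5371 probes passed through the MI-773 arrays alone and 381 through the DMSO arrays alone. Over probes well above background on all 6 arrays, the dimmest of 4 such bins held 3361 rises and 2162 falls, with a median of 0.21, and the brightest 1075 and 4614, with a median of -0.40. Over all probes without a filter, the median was -0.03 in the dimmest bin, 1.07 in the second, with 9016 rises and 1420 falls, and -0.38 in the brightest. After quantile normalization over all 60924 probes, the dimmest bin of tested probes held 4284 rises and 2300 falls and the brightest 2796 and 3576.

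**Figure D3:**
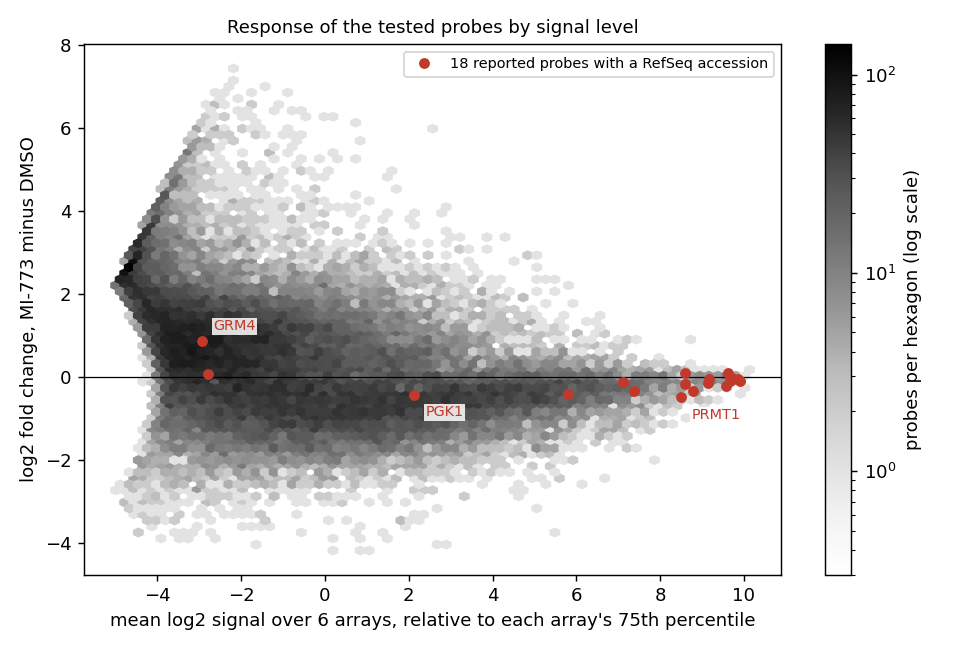
Log2 fold change (MI-773 minus DMSO) of the 40119 tested probes against their mean log2 signal over the 6 arrays, relative to each array's 75th percentile; shading gives probes per hexagon on a log scale and red points the 18 reported probes with a RefSeq accession. Rises prevail at low signal, where the set depends on the filter on dim probes, and small falls at high signal, a balance that moves with the scaling, and most named genes lie at the bright end close to 0.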

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

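The tests in this part, on the negative controls, the slide, unprocessed brightness, the level-dependent curve and the splits of the arrays, were chosen only after the result was seen. Control sequences without an intended human target were outside the comparisons above. Of 96 such sequences (negative controls, the E1A, ERCC and ETG series and 3xSLv1), 86 were well above background in most of their spots on no array, 6 on all 6 arrays, 4 on all 3 MI-773 arrays and no DMSO array, and 0 the other way. The 4 drew attention because they gave signal that the vehicle arrays did not show. Negative016 had a background-subtracted signal of 67.9 ± 7.29 after MI-773 and 2.46 ± 1.49 after DMSO (SD, n = 3). E1A_r60_3 had 43.1 ± 2.72 against 7.04 ± 1.12, Negative010 had 27.8 ± 1.73 against 11.2 ± 2.39, and ETG05_36762 had 17.2 ± 0.45 against 6.30 ± 1.11. Of the 6 detected on all arrays, 2 were higher after MI-773 without overlap between groups, 2 were lower and 2 overlapped. Negative046 had 43.1 ± 0.25 after MI-773 against 36.0 ± 5.93 after DMSO and Negative059 had 30.5 ± 5.30 against 22.4 ± 1.60. Running the opposite way, ETG05_66023 had 42.0 ± 3.02 after MI-773 against 93.3 ± 11.2 after DMSO and E1A_r60_a22 had 34.2 ± 1.29 against 48.8 ± 0.31. Outside the 96 lie the DCP sequences, whose targets are not given in the sources used here. All 5 detected on all 6 arrays were also lower after MI-773 without overlap, such as DCP_22_0 with 35.6 ± 3.85 against 47.7 ± 1.58. DCP_22_9 was well above background on all 3 DMSO arrays and no MI-773 array (12.4 ± 2.47 against 19.8 ± 0.81). Rat and mouse probes for GAPDH and PGK1 went both ways. Rat-GAPDH_3 had 97.7 ± 8.25 after MI-773 against 35.6 ± 3.21 after DMSO. Mouse-PGK1_3 had 1519 ± 47.8 against 1003 ± 112, but Mouse-GAPDH_3 had 631 ± 33.6 against 915 ± 28.3. These comparisons were made after the values were seen.

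The surplus of rises among dim probes and of falls among bright ones bears on many directions in these data; the median of the dimmest bin was 1.24 over the tested probes and 0.21 over probes well above background on all 6 arrays, 2 sets that differ in level and that the change itself helps to select, and without a filter the second bin had a median of 1.07. A higher general background on the MI-773 arrays is argued against by the median background-subtracted signal of the 60 negative-control sequences, which was lower there by -1.72 with no overlap between groups, although more negative-control spots were well above background (8.61% to 8.89% against 4.17% to 4.72%). For the slide, the contrast of dim with bright probes was taken over probes well above background on all 6 arrays. DMSO replicate 1, on the slide of the MI-773 arrays, covered 10.1% of the distance from the other DMSO arrays to them. This speaks against the slide, but it rests on 1 array and does not exclude it. Replacement values for dim spots are argued against by unprocessed brightness, where the dimmer 50% of all 60924 probes, without a filter, exceeded the negative controls by 6.92 units more after MI-773 (10.4 ± 0.38 against 3.50 ± 0.50; SD, n = 3). Cross-hybridization, differences in RNA input, amplification or labelling between the groups, and an effect of MI-773 itself remain open and untested.

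The number of probes past the threshold was weighed against a smooth level-dependent curve between arrays and against chance. After cyclic loess, which removes such a curve, 77.3% of the calls kept their direction and passed again, which argues against a curve as the whole cause. The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. In limma, 1 of them, the real one, gave 31594 calls, against a highest of 0 in the others (255 at an unadjusted p under 0.05). Every other split mixes the groups, so their difference widens its residual spread and few calls can result. The splits therefore add nothing beyond the difference between the groups and cannot decide on chance. Any difference in handling that coincided with treatment stays open.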

How the results depend on the processing

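The count of changed probes stayed within 1.5 times of 31594 in all 21 other settings of the fit, from 23892 (probes well above background on all 6 arrays, fewer probes tested) to 37569 (no filter), and from 29002 to 31230 with 1 array left out; settings chosen after seeing the data were normexp on median signals, scaling on the RefSeq probes, cyclic loess, slide 1 alone, the other detection call and the 2 other probe sets for the bins by level. Requiring a fitted difference of at least 2-fold, without bounds, left 16989, or 17007 at an unadjusted p. Median scaling gave 10859 higher and 21601 lower probes (6211 and 13608 at 2-fold), and testing probes well above background on all 6 arrays gave 10084 higher, 42.2% of its calls (4815 at 2-fold). At 2-fold, the authors' log2 table gave 7317 higher, normexp on median pixel signals 2628 higher and 2908 lower, and the percentile over probes well above background on all 6 arrays 3392 lower. The normexp counts include the shrinkage by its offset. The median log2 fold change of the dimmest of 4 bins, 1.24, was 0.21 over probes well above background on all 6 arrays and -0.0334 without a filter. The detection difference was 13.7 points with the scanner's other detection call. Across the reported genes and 4 numbered probes, 360 of 461 checks kept direction and call, 29 lost the call (4 of them with a turned sign), 42 gained it (15 with a turned sign) and 30 turned sign without passing in either setting. Under cyclic loess the sign turned for RPLP1 (0.2939), ACTB (0.2560), COX4I1 (0.3157), GAPDH (0.1445), H3-3A (0.2319), MTX1 (0.0003), ODC1 (0.2731), DYNLL1 (0.2045), ARHGDIA (0.0521), PFN1 (0.0326), RPL10 (-0.6371), RACK1 (0.3297) and RPS18 (0.2438). With the percentile over probes well above background on all 6 arrays the sign turned for RPLP1 (0.2389), ACTB (0.1950), COX4I1 (0.2408), GAPDH (0.0813), H3-3A (0.1566), ODC1 (0.1638), DYNLL1 (0.1165), RACK1 (0.2701) and RPS18 (0.1903). Under scaling on the 20 RefSeq probes the sign turned for RPLP1 (0.0825), ACTB (0.0386), COX4I1 (0.0844), H3-3A (0.0002), ODC1 (0.0074), RACK1 (0.1137) and RPS18 (0.0339). Some turned signs follow from that scaling itself, which sets the mean change of the 20 probes to 0. With the authors' log2 table the sign turned for COX4I1 (0.0826), ODC1 (0.2438), DYNLL1 (0.0296), ARHGDIA (0.0007), RPL10 (-0.5201) and RACK1 (0.0137). Under quantile normalization the sign turned for COX4I1 (0.0731), ODC1 (0.2239), DYNLL1 (0.0136), RPL10 (-0.5485) and RACK1 (0.0153). With median scaling the sign turned for ACTG1 (-0.5463), EIF3D (-0.5330) and RPL10 (-0.5704). With the slide as a block and with slide 1 alone, which both rest on DMSO replicate 1, the sign turned for ODC1 (0.0146) and RPL10 (-0.0026). Under array weights the sign turned for RPLP1 (0.0109). With normexp the sign turned for RPL10 (-0.0055). The cause was not tested. The replicate numbers gave no sign of pairing the samples (same-number correlations of -0.19, -0.03 and -0.17, and no array correlated best with its own number). These correlations use values centred within groups of 3 arrays and depend on each other, so they cannot show that the samples were unpaired. With the replicate block 29740 probes passed, and PGK1 had the same difference at a limma adjusted p of 0.051. Estimation of the array weights stopped before it converged, with weights from 0.278 to 83.4, so the arrays counted very unequally in that fit. Class counts, list tests, the scan block and limma fits on further probes per gene were not run. Signals near background limit what can be said of the 16602 probes that were well above it on no array.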

Other observations

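Both tests in this part were written down before their results were seen, but the pattern itself was noticed first. Log2 fold changes of probes with adjacent manufacturer's numbers were more correlated than shuffled numbers gave. Over 28005 adjacent pairs, r was 0.17 across probes, while 1000 shuffles of the numbers reached at most 0.02. The permutation p was 0.001, the smallest they can give, and probes are not independent replicates. The direction was the same in 56.8% of pairs, for which no chance share was computed. The correlation was 0.11 between numbers 2 apart, 0.05 at 5 apart, 0.04 at 10 apart and 0.01 at 100 apart. Position on the array is argued against, since adjacent spots correlated at 0.009, 5.39% of the value for adjacent numbers. A shared signal level accounts for part of it at most: after removing the median change at each level, 59.0% of the correlation remained. A candidate explanation is that neighbouring numbers mark transcripts of 1 locus; this needs the probe annotation and was not tested.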
